A study of Mus musculus with 4 samples.

How the data were processed

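The series holds 4 droplet-based single-cell RNA libraries (10x Genomics) of CD45-positive mouse cells, 1 each from KO bone marrow, WT bone marrow, KO tumor and WT tumor, and each pooled from 3 mice per the labels. The deposited matrices hold raw UMI counts per gene and barcode, written by Cell Ranger 3.1.0 (bone marrow) and 6.0.2 (tumor) per the file headers. The submitters' processing notes name Cell Ranger 6.1.2, Seurat 4.3.0, R 4.2.1 and mm10 or GRCm38 as builds, without saying which step used which. The bone marrow matrices list 31053 features under 31017 symbols and the tumor matrices 32285 under 32245, and features with the same symbol were summed. The smallest barcode total was 500 or 501 UMIs in every library, so a minimum had been applied before deposit. Because the versions and features differ between the tissues, each tissue was analysed separately. Coordinates come from the GENCODE M21 annotation of GRCm38.

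Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept. Doublets were marked with the scrublet method in scanpy 1.11.5 and removed, which took 3.74% (KO bone marrow), 4.97% (WT bone marrow) and 8.37% (KO tumor) of barcodes at its automatic threshold. In the WT tumor library that threshold marked 0.00831%, which was read as a failure, and the barcodes with the highest scores were removed instead, at the rate expected for its number of barcodes (9.62%). This fallback was not part of the design fixed beforehand. Cells of a tissue were clustered with both libraries together on 2000 variable genes, 30 principal components and 15 neighbors (Leiden, resolution 1, igraph 0.11.9, seed 0). S100a8, S100a9, sex-linked, mitochondrial, ribosomal protein, hemoglobin and receptor variable genes were kept out of the variable genes. Clusters were named from 21 marker lists and 4 lymphocyte subset lists, and a cluster with under 3 detected markers, with leading genes of another class, or with low depth and no leading marker stayed unnamed or mixed. The names are a reconstruction and can differ from those of the authors. No deposited annotation of cells was used here. Values for tumor monocyte-like and macrophage-like clusters are given together only, a choice made after the data were seen, because cluster 1, with 2100 KO and 137 WT cells, scored 0.675 for monocyte and 0.672 for macrophage markers.

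For each class with at least 100 cells in each library, raw UMI counts were summed per library and scaled to the total of the class as CPM. With 1 library per group no test is possible, and no p-value or standard error was computed, because cells are not replicates. Shares of cells carry exact Clopper-Pearson intervals, UMI sums exact Poisson intervals, ratios of UMI levels exact conditional intervals, and ratios of shares Katz log intervals, all at 95% and for counting error only. A gene with no UMI in a library was set to a floor of 3 UMIs over the class and its ratio given as a lower bound. Genes with at least 50 UMIs over both libraries were measured.

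The named genes follow a rule. S100a8 and S100a9 are named in the classes compared. For each class with at least 200 cells in each library, the rule takes the 3 genes with the highest and the 3 with the lowest ratio among genes with at least 50 CPM in either library, at least 100 UMIs in all, and a level of at least 0.2 of that in the class where the gene is highest. Mitochondrial, ribosomal protein, hemoglobin, immunoglobulin, T cell receptor, sex-linked and numbered predicted genes were left out. From each list described, up to 4 members with the largest ratios can be named among those with at least 100 UMIs in all and the same floor of 0.2, with no floor in CPM, and the text gives a selection of both kinds. S100a13, S100a1 and S100a7a near S100a8, and the genes shared by both tissues, are given in addition, the latter chosen after their values were seen, by a rule that asks for the same direction in all compared classes where the gene reaches 0.2 of its highest level, with at least 3 such classes and a median log2 ratio beyond 0.58 in each tissue. Stefin, granzyme, Ifit3 and Ifit3b, and H2-Q genes are near-identical copies, and the counting can have split their UMIs.

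There were 22 gene lists: other S100 genes, primary granule, secondary and tertiary granule, neutrophil maturation and egress, NADPH oxidase, myeloid suppressor, tumor-associated macrophage, type I interferon response, interferon gamma response and antigen presentation, inflammatory cytokines and NF-kB targets, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, S phase, G2 and M phase, myeloid transcription factors, dissociation and immediate early, apoptosis and p53, cytotoxic effector, T cell exhaustion and checkpoint, naive or stem-like T, regulatory T program, and sex-linked. S100a8 and S100a9 were in none. A list's median log2 ratio (KO over WT) was set against 10000 random lists of the same size matched on mean expression over 20 bins, as a description of these libraries. The printed value is the list's median less the median of its random lists. This relative form was chosen after the all-gene medians were seen to lie away from 0. Over all lists and classes, 104 of 205 list medians in bone marrow and 123 of 230 in tumor lay outside the 95% range of their random lists. Lists of genes that vary independently would put 10.25 and 11.5 there. Genes of a real list can move together, and some tumor classes are parts of others, so these are not the numbers to be had by chance. In at least 1 alternative setting 69 and 64 of the list medians outside came back inside the range or changed side, 35 and 40 of them with list genes under 0.2 of their highest level left out. The report gives a selection of the lists. The value of 1 list member is not reported here.

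The gene lists, marker lists, rule for named genes, filters and most alternative settings were fixed before the data were examined. The alternatives varied the filters, doublet removal, clustering resolution, variable genes, the library that defines the classes, the scaling, depth (each cell thinned to the 20th percentile of its class) and the minimum of UMIs. Leaving out list genes under 0.2 of their level in the class where highest, leaving out the interferon-led clusters, and shares among cells other than neutrophils were added after the data were seen.

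The computation was tested on simulated KO against WT bone marrow libraries with 12574 genes. The interval held the true fold for 100% of 53 genes at a fold of 0.25, 93.8% of 48 at 0.5, 91.5% of 47 at 2, 92.3% of 52 at 4, and 95.1% of 12374 unchanged genes. A list of 20 genes set 4-fold higher lay at percentile 100, and 4% of 200 unchanged lists lay outside the 95% range. The genes were simulated independently of one another, which real lists need not be. The counts were Poisson draws of whole-library sums, which is the model that the intervals assume. Coverage near 95% therefore checks the computation only. Spread between cells was not simulated, so the test does not show that intervals of the real classes are wide enough. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9.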

Results

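Single-cell RNA profiles were compared between mice that lack S100a8 in blood-forming cells (floxed S100a8 with Vav-Cre, called KO here) and floxed controls without Cre (called WT here). S100a8 and S100a9 encode the paired calcium-binding proteins of calprotectin, which neutrophils hold in large amounts. By its title, the series concerns how disturbing these proteins in bone marrow bears on myelopoiesis and on immunity against tumors. CD45-positive cells, that is, leukocytes, were sorted from bone marrow of tumor-free mice and from tumors of LLC, a mouse Lewis lung carcinoma line. Each of the 4 groups is 1 droplet library pooled from 3 mice. The libraries held 11070 barcodes and 51776813 UMIs (KO bone marrow), 8126 and 32906493 (WT bone marrow), 11836 and 111214201 (KO tumor), and 12027 and 102548178 (WT tumor). After filtering, 10440, 7562, 10429 and 10474 cells remained, with medians of 2770, 2256, 7947 and 6395 UMIs per cell. With 1 library per group, no difference below has a replicate check or a test. Intervals are 95% intervals that cover counting error only, and they leave out the spread between mice, sorts and libraries. Those of UMI levels and their ratios also leave out the spread between cells, because all UMIs of a class were counted as independent. Cell classes were rebuilt by clustering and are called "-like" for that reason.

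S100a8 (ENSMUSG00000056054, GRCm38 chromosome 3, 90668978 to 90670035, plus strand, a protein-coding gene) was measured first, as the check of the genotype labels. In bone marrow the KO library held 6 S100a8 UMIs, or a level of 0.122 CPM (UMI counts scaled to the total of the library or class, 0.0449 to 0.266), against 2063889 UMIs, or 68324 CPM, in the WT library. WT immature neutrophil-like cells held 180186 CPM, so that S100a8 alone took 18.0% of their UMIs, and WT mature neutrophil-like cells held 131805 CPM. In tumor the KO library held 84 S100a8 UMIs, 0.902 CPM (0.719 to 1.12), and the WT library 11153, or 133 CPM (131 to 135), a 147-fold difference (119 to 185). It was 343-fold as a mean over cells, and 19-fold with cells thinned to 3806 UMIs, which leaves out 2069 KO and 2108 WT cells below that depth. Of the KO tumor UMIs, 69 came from 1 mature neutrophil-like barcode. In both tissues the library labelled KO was the one with S100a8 near absent. Free RNA was abundant: 94.3% of WT bone marrow B-lineage-like cells, which should lack the gene, had an S100a8 UMI at a median depth of 1585 UMIs, against 100% of WT mature neutrophil-like cells at 1402.5.

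The neighboring partner gene S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721, minus strand) was present in both KO libraries. It stood at 193171 CPM in KO and 148494 CPM in WT immature neutrophil-like cells of bone marrow, 1.30-fold higher in KO (1.30 to 1.30), and at 142927 and 123424 in mature ones, 1.16-fold higher (1.15 to 1.16). With S100a8, S100a9 and the mitochondrial, ribosomal and hemoglobin genes left out of the total, these ratios were 1.08 and 1.01. In the whole tumor library S100a9 was 25.1-fold higher in KO (24.8 to 25.4), at 6637 against 264 CPM, but 17.2-fold as a mean over cells and 185-fold with the same thinning, whose depth exceeds the median of 2417 UMIs of WT tumor neutrophil-like cells. Within tumor mature neutrophil-like cells it was 1.22-fold higher (1.20 to 1.24), at 45437 against 37206 CPM. S100a6, another gene of the same S100 cluster on chromosome 3 (90612882 to 90624181), was 5.44-fold higher (5.37 to 5.51) in KO bone marrow immature neutrophil-like cells, at 16630 against 3057 CPM.

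**Figure D1:**
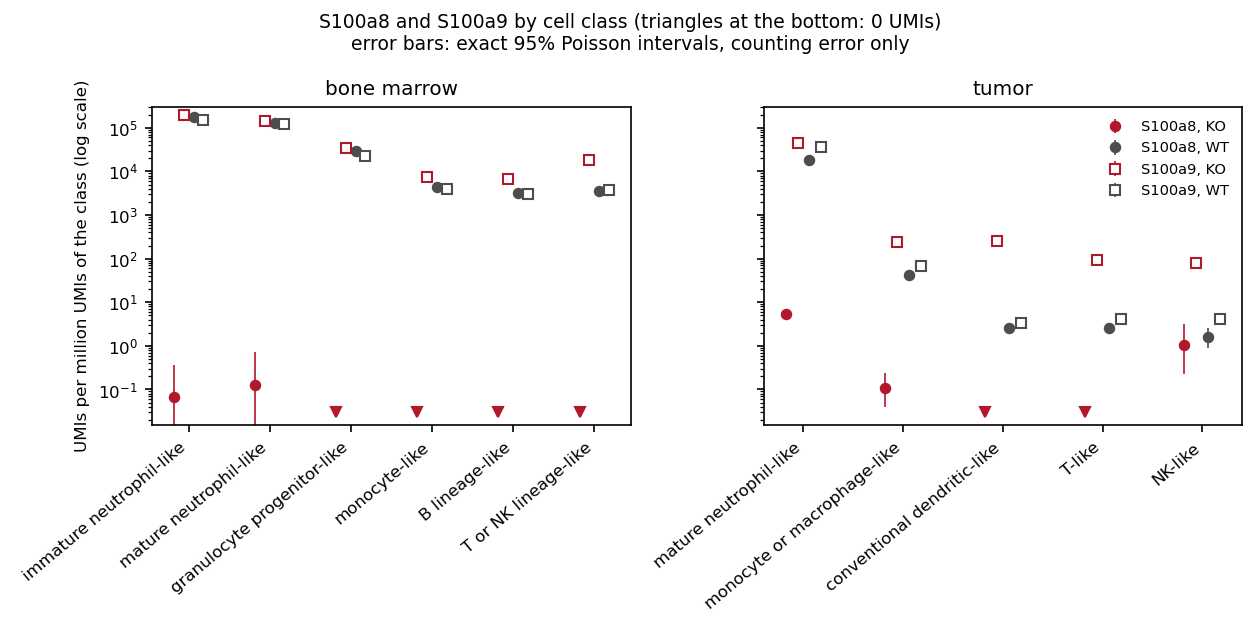
Levels of S100a8 and S100a9 (CPM, log axis) in the KO and WT libraries of bone marrow and tumor, per cell class, with 95% Poisson intervals as error bars. S100a8 is near absent from both KO libraries, while S100a9 in bone marrow immature neutrophil-like cells stands at 193171 in KO and 148494 in WT.

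In bone marrow, the KO library held more neutrophil-like and fewer B-lineage-like cells. Neutrophil-like cells made up 66.5% of KO cells (exact binomial interval 65.6 to 67.4) and 46.6% of WT cells (45.5 to 47.8), a ratio of 1.43 (1.39 to 1.47). The mature ones stood at 36.8% (35.8 to 37.7) against 20.7% (19.8 to 21.6), a ratio of 1.78 (1.69 to 1.87). Immature ones stood at 29.8% (28.9 to 30.7) against 26.0% (25 to 27), a ratio of 1.15 whose direction turned in 4 of the alternative settings. B-lineage-like cells stood at 8.55% (8.02 to 9.11) against 26.0% (25 to 27), 3.03-fold lower in KO (2.82 to 3.27). B precursor-like cells, which carry the pre-B receptor and recombination genes, were 3.59-fold lower (3.26 to 3.96), and B-like cells 2.27-fold lower (2.00 to 2.57). Granulocyte progenitor-like cells stood at 5.57% (5.14 to 6.03) in KO and 5.47% (4.97 to 6.01) in WT, and hematopoietic stem and progenitor-like cells at 2.16% (1.89 to 2.46) and 2.59% (2.25 to 2.98), with overlapping intervals in both cases. The stem and progenitor-like class is cluster 15, which scored 1.86 for these markers and 1.80 for megakaryocyte or platelet markers. Its leading genes include Pf4, Ppbp and Itga2b. Monocyte-like cells stood at 4.98% (4.57 to 5.42) and 5.82% (5.30 to 6.37), T-like or NK-like cells at 3.66% (3.31 to 4.04) and 4.19% (3.75 to 4.67), and plasmacytoid dendritic-like cells at 2.5% (2.21 to 2.82) and 3.19% (2.80 to 3.61). Since shares sum to the whole, these were recomputed among cells other than neutrophils: B-lineage-like cells remained lower in KO (ratio 0.525, 0.492 to 0.561), with B precursor-like cells at 0.444 and B-like cells at 0.703, whereas monocyte-like (1.36), T-like or NK-like (1.39) and plasmacytoid dendritic-like cells (1.25) were then higher, as were granulocyte progenitor-like cells (1.62, 1.44 to 1.83) and stem and progenitor-like cells (1.33, 1.11 to 1.60).

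**Figure D2:**
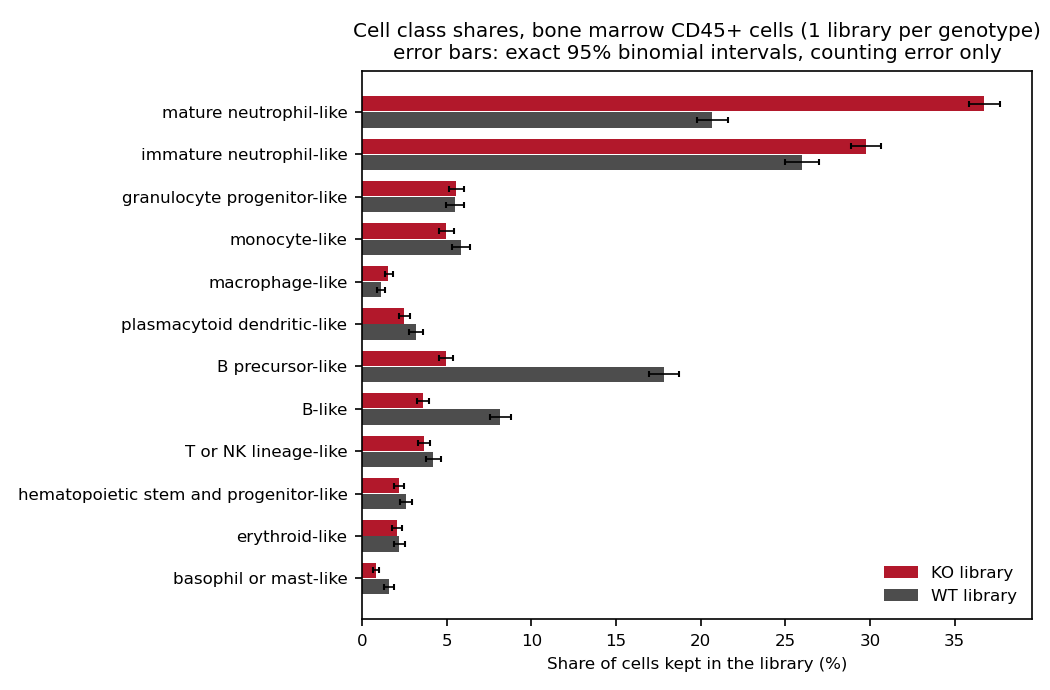
Share of cells (percent, axis from 0) in each class of the KO and WT bone marrow libraries, with exact binomial 95% intervals. Mature neutrophil-like cells stand at 36.8% in KO and 20.7% in WT, and B precursor-like cells at 4.96% and 17.8%.

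Within bone marrow neutrophil-like cells, genes of the type I interferon response were lower in the KO library. The all-gene median log2 ratio was 0.22 in immature and 0.21 in mature cells (−0.04 and 0.01 once S100a8, S100a9 and the other abundant genes were left out of the total), so list medians are given relative to random lists matched on expression. In immature cells the interferon list lay at −0.58 on this log2 scale (random lists −0.08 to 0.08, percentile 0): 39 of 40 measured members lay below the class median and 18 by more than 1.5-fold. It lay at −0.31 (percentile 0) over the 23 genes left once those under 0.2 of their highest level were left out. Among them, Usp18 stood at 9.32 against 16.6 CPM (1.78-fold lower, 1.40 to 2.27), Oas1g was 1.76-fold lower (1.40 to 2.22) and Slfn8 1.70-fold lower (1.45 to 1.99), while Ifit2 was 1.65-fold higher (1.22 to 2.26). In mature cells the list lay at −0.34 (percentile 0), with Ifi27l2a at 1217 against 2977 CPM (2.45-fold lower, 2.37 to 2.52) and Ifit3 2.33-fold lower (1.87 to 2.90), or 1.05-fold without the interferon-led cluster 10. Clusters 1, 2, 8 and 10 hold the mature class, with 1547, 1458, 517 and 315 KO cells against 614, 578, 131 and 241 WT cells.

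Among granule genes of bone marrow neutrophil-like cells, some lists lay inside the range of random lists and others below it. In immature cells the primary granule list lay at 0.00 (percentile 53) with 8 of 11 members above the class median, but at 0.16 (percentile 98.95) with classes defined by the WT library alone, and the secondary and tertiary granule list at −0.03 (percentile 21.9). In mature cells the secondary and tertiary granule list lay at −0.16 (percentile 1.30), with Anxa1, which encodes annexin A1, 1.63-fold higher (1.57 to 1.70) and 12 of 22 members below the class median. It lay at −0.27 with thinned cells, but inside the random range with genes under 0.2 of their highest level left out (−0.036, percentile 33.1), with doublets kept (0.066, percentile 81.6) and with classes defined by the WT library alone (−0.12, percentile 4.46). The list of maturation and egress genes lay at −0.17 (percentile 1.42), but inside the random range with thinned cells (percentile 8.24) and as a mean over cells (3.09). It holds Stfa2, a stefin, at 267 against 27.9 CPM, 9.55-fold higher (7.51 to 12.3), or 18.2-fold without cluster 10. The related stefin-like BC100530 was 7.17-fold higher (6.34 to 8.13), and over both neutrophil-like classes Stfa1 was 4.57-fold higher (4.22 to 4.96). Stefin genes are near-identical copies whose UMIs can be assigned to one another, and they also lead cluster 2 of the mature class. Retn, which encodes resistin, was 7.51-fold lower (5.52 to 10.3) and Slc25a33 2.66-fold lower (2.09 to 3.38), while Steap4, which is among the leading genes of cluster 8, was 3.95-fold higher (2.92 to 5.45). The NADPH oxidase list lay at 0.15 (percentile 92.0), oxidative phosphorylation at 0.07 (percentile 95.4) and apoptosis and p53 at −0.08 (percentile 23.2), each inside the range of random lists. Oxidative phosphorylation lay above that range with thinned cells (0.13, percentile 99.15), at least 200 UMIs per gene, doublets kept (0.17) or classes defined by the WT library alone (0.12). The G2 and M phase list lay at −0.13 in immature cells (percentile 0) and −0.28 with thinned cells, but at 0.041 (percentile 93.0) with doublets kept and inside the random range with classes defined by the WT library alone (percentile 3.17). It lay at −0.45 in mature cells (percentile 0) and −0.27 with thinned cells, but at −0.062 (percentile 28.4) with at least 200 UMIs per gene and at 0.14 (percentile 87.4) once genes under 0.2 of their level in the class where highest were left out. The S phase list lay at −0.08 in immature cells (percentile 4.87), inside the random range, and below that range with thinned cells (−0.29, percentile 0). In mature cells it lay at −0.52 (percentile 0.06), or −0.29 (percentile 1.78) with classes defined by the WT library alone.

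Genes that answer to cell handling were higher in the KO neutrophil-like cells of bone marrow. The dissociation and immediate early list lay at 0.32 in immature cells (percentile 100) and 0.22 in mature cells (percentile 99.9), the latter at 0.38 with thinned cells and 0.35 with genes under 0.2 of their highest level left out. In immature cells Egr1, an immediate early transcription factor, stood at 146 against 27.9 CPM, 5.25-fold higher (4.59 to 6.04), and Jun 2.33-fold higher (2.07 to 2.62). The myeloid suppressor list lay at 0.21 in immature cells (percentile 100), with 22 of 25 members above the class median, and at 0.36 with thinned cells. Its members include Cd14, the lipopolysaccharide co-receptor, 4.77-fold higher (3.09 to 7.70; 7.41-fold with doublets kept and 8.42-fold with classes defined by the WT library alone), and Ifitm2, 2.10-fold higher (1.98 to 2.22). The list of other S100 genes lay at 0.13 (percentile 90.4) over 7 genes, with S100a1 2.16-fold higher (1.86 to 2.5) and S100a13 1.94-fold higher (1.83 to 2.05). It lay above the random range with thinned cells (0.65, 5 genes), at least 200 UMIs per gene (0.73, 4 genes), with genes under 0.2 of their highest level left out (0.73, 4 genes) or classes defined by the WT library alone (0.35), and at 0.030 (percentile 60.4) with doublets kept. Myeloid transcription factors lay at −0.10 (percentile 2.38) with 13 members above and 15 below the class median, but inside the random range in 6 alternative settings (percentiles 3.74 to 63.7), in 1 of them above 0 (0.017). By the rule over all genes of at least 50 CPM, Ddx60, Klhdc4 and Slfn4 were the 3 lowest in immature cells, at 1.51-fold (1.35 to 1.68), 1.49-fold (1.32 to 1.68) and 1.46-fold lower (1.37 to 1.54).

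The interferon list was also lower in the other bone marrow classes compared, apart from stem and progenitor-like cells. It lay at −0.55 in monocyte-like, −0.53 in plasmacytoid dendritic-like, −0.26 in B precursor-like and −0.26 in B-like cells (percentiles 0, 0, 0.02 and 0). It lay at −0.20 in granulocyte progenitor-like cells (percentile 0), −0.32 in erythroid-like cells (percentile 0) and −0.18 in T-like or NK-like cells (percentile 0.74), and at −0.08 in stem and progenitor-like cells (percentile 8.22). With thinned cells the list lay inside the random range in B-like (percentile 2.64), erythroid-like (13.1) and T-like or NK-like cells (37.4), the last also with classes defined by the WT library alone. As a mean over cells it did so in granulocyte progenitor-like (4.31) and erythroid-like cells (6.52), and with at least 200 UMIs per gene in B-like cells (8.34). Over the alternatives it ranged from −0.16 (classes defined by the WT library alone) to −0.51 (with genes under 0.2 of their highest level left out) in B precursor-like cells and from −0.083 (mean over cells) to −0.36 (classes defined by the WT library alone) in granulocyte progenitor-like cells. In stem and progenitor-like cells the list lay below the random range as a mean over cells (−0.29, percentile 0.03). With thinned cells it lay above 0 there, inside that range (0.031, percentile 61.8). In monocyte-like cells 48 of 51 members lay below the class median, with Ifit3 2.52-fold lower (1.72 to 3.74), Usp18 2.32-fold lower (1.76 to 3.07) and the antiviral GTPase gene Mx1 1.99-fold lower (1.46 to 2.71). In plasmacytoid dendritic-like cells, the main producers of type I interferon, Ifi44 was 2.06-fold lower (1.41 to 3.02) and Irf7, a transcription factor that induces interferon genes, 1.88-fold lower (1.53 to 2.31). The list of interferon gamma response and antigen presentation lay at −0.36 there (percentile 0), with 26 of 30 members below the class median. Cell cycle lists were higher in KO in these cells, at 0.59 for G2 and M phase (45 of 46 members above the class median) and 0.35 for S phase (33 of 35), each at percentile 100, the latter at 0.55 as a mean over cells and 0.22 with classes defined by the WT library alone. Cdk1, the kinase that drives entry into mitosis, was 2.26-fold higher (1.65 to 3.15), and Cdc20 2.11-fold higher (1.42 to 3.20). Neutrophil transcripts were higher in the same cells, with S100a9 at 6627 against 2903 CPM, a ratio of 2.28 that was 1.04 with doublets kept. The secondary and tertiary granule list lay at 0.83 there, but at 0.43 as a mean over cells and −0.21 (percentile 0.07) with doublets kept. The maturation and egress (0.54) and primary granule lists (0.52) lay inside the random range with thinned cells (percentiles 66.7 and 93.9), the former also with doublets kept (94.0) and the latter as a mean over cells (87.9) or with classes defined by the WT library alone (94.0). The maturation and egress list lay below 0 with at least 200 UMIs per gene (−0.014) or with genes under 0.2 of their highest level left out (−0.045). The secondary and tertiary granule list also lay at 1.25 in stem and progenitor-like, 0.98 in B precursor-like, 0.33 in erythroid-like and 0.27 in monocyte-like cells (percentile 100 for each). It lay at 0.53 in B precursor-like cells with doublets kept and 0.72 in erythroid-like cells as a mean over cells, and inside the random range in monocyte-like cells with doublets kept (percentile 95.7) or with genes under 0.2 of their highest level left out (0.016, percentile 56.7, 5 genes).

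Commd10 (ENSMUSG00000042705, chromosome 18, 46958816 to 47234284, plus strand) was the highest named gene of both monocyte-like cells (63.5 against 14 CPM, 4.52-fold higher, 2.96 to 7.19, or 7.68-fold with thinned cells) and plasmacytoid dendritic-like cells (60.0 against 9.22 CPM, 6.51-fold higher, 3.40 to 14, or 10.3-fold as a mean over cells). Only the KO mice carry Vav-Cre, so this difference cannot be assigned to the loss of S100a8 alone. In monocyte-like cells Tppp3 and Pla2g7 followed, at 3.60-fold (2.75 to 4.77) and 2.94-fold higher (2.33 to 3.75). In B precursor-like cells Vpreb2, which encodes part of the pre-B receptor and is among the leading genes of cluster 18, was 2.94-fold higher (2.49 to 3.47; 4.54-fold with thinned cells), and Ccnd2, which encodes cyclin D2, 2.78-fold higher (2.52 to 3.08). Cluster 18 held 173 KO and 196 WT cells of this class, whereas cluster 5 held 247 and 851 and cluster 16 held 98 and 300. Ifi27l2a was 2.77-fold lower there (2.59 to 2.96) and Glcci1 2.80-fold lower (2.27 to 3.49). In B-like cells the S phase and G2 and M phase lists lay at −0.56 and −0.62 (percentile 0 for each), but inside the random range with thinned cells (−0.041, percentile 38.4, and −0.22, percentile 2.71). The G2 and M phase list lay at −0.32 as a mean over cells, −0.29 with at least 200 UMIs per gene and −0.27 with genes under 0.2 of their highest level left out. The replication clamp gene Pcna was 2.07-fold lower (1.58 to 2.74) and Il4i1, which is among the leading genes of cluster 14 (110 KO and 317 WT cells), 2.73-fold lower (2.09 to 3.61), while Tshz1 was 2.5-fold higher (1.64 to 3.85). In T-like or NK-like cells the G2 and M phase list lay at 0.80 (percentile 100), with all 39 measured members above the class median. KO cells of this class were deeper (medians of 3485.5 and 2185 UMIs), and with thinned cells the list lay at 0.12 (percentile 87.2, 13 genes), inside the random range. With doublets kept the list lay at 0.38 (percentile 100). Cenpf was 5.27-fold higher (3.33 to 8.81), or 3.23-fold as a mean over cells and 1.79-fold with doublets kept, and Il7r, the interleukin-7 receptor gene, 2.67-fold lower (2.19 to 3.26). The secondary and tertiary granule list also lay at 1.96 in these cells (percentile 100), and at 0.72 with doublets kept. These are neutrophil transcripts, and S100a9 stood at 18097 CPM in KO and 3747 CPM in WT cells of this class, with a UMI in 99.5% and 96.2% of cells. That ratio of 4.83 was 1.94 with doublets kept. In granulocyte progenitor-like cells the named genes stayed within 1.58-fold, with AC149090.1 the highest (1.58, 1.41 to 1.77) and Snhg9 the lowest, at 1.56-fold lower (1.34 to 1.81).

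In tumor, myeloid-like cells made up 80.4% of the KO library (79.6 to 81.2) and 43.6% of the WT library (42.7 to 44.6), and lymphoid-like cells 16.9% (16.2 to 17.7) and 54.0% (53.1 to 55.0). Neutrophil-like cells made up 29.7% of KO cells (28.8 to 30.6) and 2.06% of WT cells (1.80 to 2.35), 14.4-fold higher in KO (12.6 to 16.5). Monocyte-like and macrophage-like cells together stood at 47.0% (46.0 to 48.0) against 22.0% (21.3 to 22.9), 2.13-fold higher (2.05 to 2.22). Conventional dendritic-like cells stood at 3.38% (3.05 to 3.75) against 17.9% (17.1 to 18.6), 5.28-fold lower in KO (4.73 to 5.89), or 3.47-fold with doublets kept. Clusters 7 (149 KO and 860 WT cells) and 13 (56 and 437) of this class were led by Cd209a, Mgl2, Clec10a and MHC class II genes. Mgl2 and Clec10a are also in the macrophage gene list, so the border to monocyte-like and macrophage-like cells is uncertain. NK-like cells stood at 2.54% (2.25 to 2.86) against 17.5% (16.8 to 18.3), 6.89-fold lower (6.08 to 7.82). T-like cells stood at 11.4% (10.8 to 12.0) against 29.8% (28.9 to 30.7), 2.62-fold lower (2.47 to 2.79). As shares of all cells, CD4 T-like cells were 3.56-fold lower (3.21 to 3.96; 7.13-fold at Leiden resolution 2), regulatory T-like cells 3.87-fold lower (3.27 to 4.59) and CD8 T-like cells 1.46-fold lower (1.31 to 1.62). Of lymphoid-like cells alone, however, CD8 T-like cells made up 30.5% in KO (28.4 to 32.7) and 13.9% in WT (13 to 14.9), CD4 T-like cells 23.7% (21.7 to 25.7) and 26.4% (25.3 to 27.6), and regulatory T-like cells 9.41% (8.08 to 10.9) and 11.4% (10.6 to 12.3). CD8 T-like cells thus numbered 3.25 per regulatory T-like cell in KO (2.72 to 3.89) and 1.22 in WT (1.10 to 1.36). These numbers come from the main clustering only. The KO over WT ratio of the CD8 T-like share of all cells, 0.686 there, was 0.609 at Leiden resolution 0.5 and 0.475 with the KO library clustered alone. Gamma-delta T-like or type 2 innate lymphoid-like cells were 2.59-fold lower (2.12 to 3.16) and plasmacytoid dendritic-like cells 5.44-fold lower (3.58 to 8.25). Among cells other than neutrophils the ratios were 2.97 for monocyte-like and macrophage-like, 0.264 for conventional dendritic-like, 0.202 for NK-like and 0.531 for T-like cells, and 0.956 for CD8 T-like cells (0.860 to 1.06), whose difference was then within counting error. Despite the CD45 sort, 90 KO and 61 WT cells (cluster 23) were fibroblast-like. Krt8, a gene of the carcinoma marker list, is also among the leading genes of this cluster, so it may hold other cells than fibroblasts. In addition, 1 cluster of 189 KO and 184 WT cells stayed unnamed. Clusters 18 and 21, with markers of both T and NK cells, held 169 KO and 297 WT cells and were counted in neither class.

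**Figure D3:**
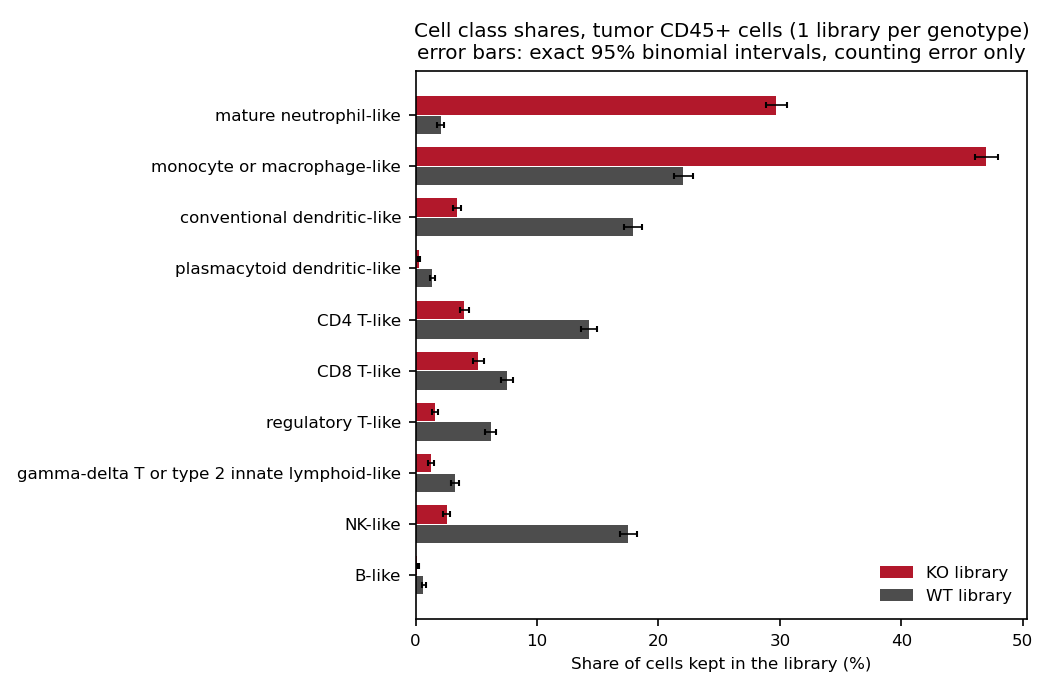
Share of cells (percent, axis from 0) in each class of the KO and WT tumor libraries, with exact binomial 95% intervals. Neutrophil-like cells stand at 29.7% in KO and 2.06% in WT, and NK-like cells at 2.54% and 17.5%.

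In tumor mature neutrophil-like cells, interferon response genes were much lower in the KO library, and inflammatory and hypoxia genes were higher. The class rests on 3097 KO cells with a median of 3796 UMIs and 216 WT cells with a median of 2417, and the all-gene median log2 ratio was −0.29. The type I interferon list lay at −1.31 relative to matched lists (percentile 0), with 42 of 47 members below the class median and 36 by more than 1.5-fold. Ifit3 stood at 40.9 against 441 CPM (10.8-fold lower, 9.22 to 12.6), the nucleic acid sensor gene Zbp1 at 101 against 640 (6.36-fold lower, 5.64 to 7.16), and Ifi27l2a was 5.77-fold lower (5.52 to 6.02). Interferon gamma response and antigen presentation genes lay at −0.74 (percentile 0). Cd274, which encodes the checkpoint ligand PD-L1, was an exception at 1192 against 508 CPM, 2.35-fold higher (2.09 to 2.65). Inflammatory cytokines and NF-kB targets lay at 0.67 (percentile 100; 27 of 30 members above the class median), with the acute-phase gene Saa3 8.99-fold higher (4.73 to 19.7) and the cyclooxygenase gene Ptgs2 2.09-fold higher (1.93 to 2.27). Hypoxia and glycolysis genes lay at 0.60 (percentile 100), with Ddit4 4.39-fold higher (2.22 to 10.2) and Ero1l 2.74-fold higher (2.34 to 3.22). Oxidative phosphorylation genes lay at −0.40 (percentile 0.05), with 47 of 58 members below the class median, or at −0.25 as a mean over cells. The myeloid suppressor list lay at 0.28 (percentile 97.6, but inside the random range at 96.7 with thinned cells and 97.49 with doublets kept), with Nos2 3.87-fold higher (1.65 to 12.0) but Prok2 3.78-fold lower (2.61 to 5.34). The growth factor gene Areg stood at 187 CPM in KO against 1.81 in WT, where it had 1 UMI, a ratio of 103 (18.5 to 4066). Id3 was 10.8-fold higher (5.49 to 25.1), and Stfa2, with no UMI in WT, at least 10.3-fold higher against a floor of 3 UMIs over the class. The dissociation and immediate early list was also higher, at 0.63 (percentile 100): Hspa1b, a heat shock gene, was 8.41-fold higher (6.73 to 10.6), and cluster 8, which it leads, held 873 KO and 54 WT cells. With thinned cells, which leaves 64 WT cells, Areg and Stfa2 had no UMI in WT and were at least 11.7-fold and at least 3.59-fold higher. Id3 then stood at 6.97-fold (2.71 to 25.6, and 7-fold with classes defined by the WT library alone), Hspa1b at 106-fold (29.4 to 877, 2 UMIs in WT) and Nos2 at 1.81-fold higher (0.610 to 8.82, 3 UMIs in WT), and Prok2 at 10.7-fold lower (6.93 to 16.2).

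Monocyte-like and macrophage-like cells of the tumor also had lower interferon and higher inflammatory genes in the KO library. The libraries filled this class from different clusters: cluster 1 (led by Serpinb2 and Cxcl1) held 2100 KO and 137 WT cells, cluster 4 held 1099 and 466, cluster 9 held 685 and 153 and cluster 12 held 374 and 140, while cluster 6 held 450 and 841 and cluster 11, led by interferon genes, 194 and 572. The all-gene median log2 ratio was −0.22. The type I interferon list lay at −0.85 (percentile 0; 49 of 53 members below the class median), or −0.50 (percentile 0) without cluster 11, with Irf7 at 94.5 against 507 CPM, 5.36-fold lower (5.19 to 5.54), and Ifit3 3.19-fold lower (2.93 to 3.47). Interferon gamma response and antigen presentation genes lay at −0.76 (percentile 0). Ciita, the transactivator of MHC class II genes, was 3.11-fold lower (2.80 to 3.45), H2-DMb1 2.79-fold lower (2.71 to 2.86) and H2-Eb1 2.43-fold lower (2.40 to 2.46). Inflammatory genes lay at 0.83 (percentile 100; 29 of 31 members above), with the neutrophil-attracting chemokine genes Cxcl1 at 1565 against 147 CPM (10.7-fold higher, 10.3 to 11.1) and Cxcl3 8.12-fold higher (7.90 to 8.34). Csf3, which encodes the granulocyte growth factor G-CSF, stood at 144 against 2.99 CPM, 48.3-fold higher (37.7 to 62.9), or 73.7-fold without cluster 11. Myeloid suppressor genes lay at 0.95 (percentile 100; 27 of 30 members above). Among these the nitric oxide synthase gene Nos2 was 28.1-fold higher (22.8 to 35.1), the prostaglandin synthase gene Ptges 25.5-fold higher (18.9 to 35.3) and the arginase gene Arg1 6.55-fold higher (6.32 to 6.80). Csf3 and Cxcl1 are among the leading genes of cluster 1 and Irf7 of cluster 11, so their ratios and the cluster sizes are not separate observations. Nos2, Ptges and Arg1 are among the leading genes of cluster 12, which held 374 of 4902 KO and 140 of 2309 WT cells of the class. The size of cluster 12 alone therefore does not give the ratios of these 3 genes. Hypoxia and glycolysis genes lay at 0.64 (percentile 100), with Vegfa 2.97-fold higher (2.85 to 3.09). Genes of alternatively activated or lipid-handling tumor macrophages lay at 0.49 (percentile 100), or 0.22 (percentile 99.6) without cluster 11, but went both ways: Retnla was 5.55-fold lower (4.90 to 6.29; 14.2-fold as a mean over cells) and Mgl2 4.16-fold lower (3.95 to 4.38). Mgl2 and H2-DMb1 are among the leading genes of cluster 6 here and of conventional dendritic-like clusters 7 and 13. Their ratios and the shares of these classes are therefore not separate observations. Ly6c2, a marker of inflammatory monocytes, was 4.80-fold lower (4.73 to 4.88). The secondary and tertiary granule list lay at 0.93 (percentile 100), or 1.53 without cluster 11, and S100a9 stood at 241 against 67.2 CPM. The cytotoxic effector list lay at −1.09 (percentile 0), at −0.50 with doublets kept, and at 0.59 (percentile 96.9, 3 genes) once genes under 0.2 of their level in the class where highest were left out.

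**Figure D4:**
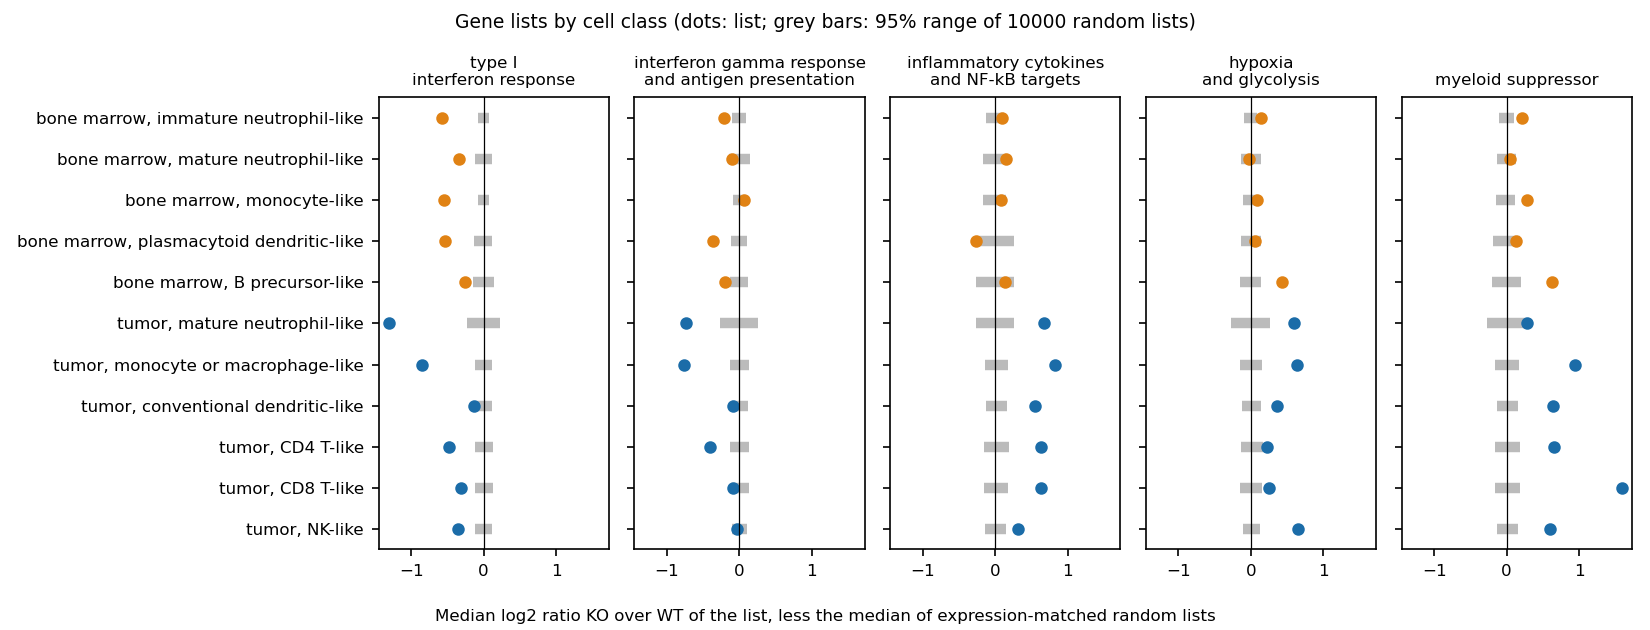
Median log2 ratio (KO over WT) of gene lists relative to expression-matched random lists, per cell class, with the 95% range of the random lists as bars. The type I interferon list lies below the random range in tumor neutrophil-like (−1.31) and monocyte-like or macrophage-like cells (−0.85, or −0.50 without the interferon-led cluster) and in bone marrow immature neutrophil-like cells (−0.58, or −0.31 with genes under 0.2 of their highest level left out).

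In conventional dendritic-like cells the interferon list lay at −0.14 (percentile 0.32), with Irf7 2.33-fold lower (2.08 to 2.62), or at −0.22 with at least 200 UMIs per gene or with genes under 0.2 of their highest level left out and −0.30 with doublets kept. The inflammatory list lay at 0.55 (percentile 100; 27 of 30 members above), or 1.28 with doublets kept and 0.26, inside the random range (percentile 96.0), with genes under 0.2 of their highest level left out. Clu was the highest named gene there, 4.63-fold (3.98 to 5.40; 2.83-fold as a mean over cells and 2.75-fold with doublets kept), followed by Cystm1 at 3.68-fold (3.27 to 4.14; 2.02-fold with doublets kept), and Cd209d, among the leading genes of cluster 7 of this class, the lowest, 2.48-fold lower (2.09 to 2.95). S phase and G2 and M phase genes lay at −0.40 and −0.42 (percentile 0 for each), the latter at 0.095 with doublets kept and −0.11 (percentile 18.1) with genes under 0.2 of their highest level left out. The secondary and tertiary granule list lay at 2.01 (percentile 100), but at 1.29 with classes defined by the WT library alone, 0.44 with at least 200 UMIs per gene and −0.013 (percentile 46.5) with genes under 0.2 of their highest level left out. S100a9 had a UMI in 60.3% of KO and 3.37% of WT cells of this class, at median depths of 14541 and 12216 UMIs.

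In tumor CD4 T-like cells, interferon response genes and Ifng were lower and naive or stem-like genes higher in the KO library. The type I interferon list lay at −0.48 and the interferon gamma list at −0.40 (percentile 0 for each), with Gbp3 4.01-fold lower (2.78 to 5.97). Ifng, the interferon gamma gene, stood at 46.2 against 212 CPM, 4.58-fold lower (3.75 to 5.64), and the chemokine gene Ccl5 was 2.69-fold lower (2.57 to 2.81). With classes defined by the WT library alone these were 2.61-fold and 1.58-fold lower. The naive or stem-like list lay at 0.70 (percentile 100; 12 of 16 members above), with Il7r 2.79-fold higher (2.60 to 3.00), Klf2 2.20-fold higher (2.05 to 2.36) and S1pr1, the receptor for egress from tissue, 1.97-fold higher (1.75 to 2.21). The list lay at 0.38 with genes under 0.2 of their highest level left out and 0.35 with classes defined by the WT library alone. Tnfsf8, which encodes the CD30 ligand, was 5.65-fold higher (5.06 to 6.32). The cytotoxic list lay at −0.21 (percentile 0.405), −0.53 as a mean over cells and −0.65 with genes under 0.2 of their highest level left out, but inside the random range with thinned cells (percentile 10.3), at least 200 UMIs per gene (9.10) or doublets kept (33.7), and at 0.094 when the WT library alone defined the classes.

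CD8 T-like cells had the interferon list at −0.32 (percentile 0) and the cytotoxic list at 0.26 (percentile 99.9). Gzmb, the granzyme B gene, was 1.85-fold higher (1.79 to 1.92), and Gzmk 2.36-fold lower (2.12 to 2.63). The exhaustion and checkpoint list lay at 0.09 (percentile 86.0), inside the random range, with members on both sides, but above that range with thinned cells (0.28, percentile 99.9) or with genes under 0.2 of their highest level left out (0.43, percentile 100). Pdcd1, the PD-1 gene, stood at 435 against 229 CPM (1.90-fold higher, 1.76 to 2.05) and Tnfrsf9 was 2.66-fold higher (2.35 to 3.02), but Cd160 was 2.60-fold lower (2.17 to 3.12) and Tox, a transcription factor of exhausted cells, 2.00-fold lower (1.56 to 2.58). Ifitm1 was 22.5-fold higher (20.9 to 24.4), at 3234 against 143 CPM, and Il2ra 5.08-fold higher (4.28 to 6.05). In regulatory T-like cells the interferon list lay at −0.17 (percentile 0.18), or inside the random range with thinned cells (38.2) and as a mean over cells (18.7) and −0.27 with classes defined by the WT library alone, and the regulatory T program at −0.05 (percentile 22.9), with Tnfrsf4 1.34-fold lower (1.28 to 1.41) and Ccr4 1.89-fold higher (1.35 to 2.61). Gamma-delta T-like or type 2 innate lymphoid-like cells had the interferon list at −0.71 (percentile 0), with 17 of 20 members below the class median. Over all T-like cells the myeloid suppressor list lay at 1.24 (percentile 100), but at 0.74 with at least 200 UMIs per gene and 0.063 (percentile 73.1, 11 genes) with genes under 0.2 of their level in the class where highest left out. S100a9 had a UMI in 41.1% of KO and 1.67% of WT T-like cells, at median depths of 5883.5 and 5011 UMIs.

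In tumor NK-like cells, several granzyme genes and hypoxia and glycolysis genes were higher in the KO library. Gzmf stood at 2101 against 30.2 CPM, 69.5-fold higher (62.2 to 77.9; 44.9-fold with thinned cells), Gzmd was 9.20-fold higher (8.63 to 9.82) and Gzmc 2.96-fold higher (2.90 to 3.02). These granzyme genes are close copies of one another, so their UMIs can be shared, Gzmc is among the leading genes of cluster 3 of this class, and Gzmf leads cluster 21, which was kept out of it. The cytotoxic list as a whole lay at 0.06 (percentile 84.1), inside the random range. Hypoxia and glycolysis genes lay at 0.65 (percentile 100; 28 of 31 members above), with Pgk1, a glycolytic kinase gene, 1.91-fold higher (1.78 to 2.06). The exhaustion and checkpoint list lay at 0.43 (percentile 100), or 0.26 as a mean over cells, 0.17 with genes under 0.2 of their highest level left out and 0.28 with classes defined by the WT library alone, although Tox was 1.64-fold lower (1.22 to 2.26) and Eomes 1.53-fold lower (1.37 to 1.71). The interferon list lay at −0.35 (percentile 0) and, with doublets kept, at −0.024 (percentile 31.8). Cxcl10 was higher in KO within it, 1.97-fold (1.80 to 2.16). Pmepa1 and Nrarp, targets of TGF-beta and Notch signaling respectively, were 3.02-fold (2.69 to 3.40) and 2.75-fold lower (2.38 to 3.20).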

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

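The comparison of lists between the tissues within this class was chosen after the data were seen, and no explanation was tested. The S phase list of mature neutrophil-like cells lay on opposite sides of its random lists in the 2 tissues. In bone marrow its relative median was −0.52 (percentile 0.06, 17 measured genes), lower in the KO library, and in tumor it was 0.67 (percentile 97.55, 8 measured genes), higher in the KO library. The difference between the tissues was not tested. The tumor value lay inside the random range in the alternative settings that thinned the cells (percentile 92.5), took a mean over cells (96.8), kept doublets (0.41, percentile 89.7), asked for at least 200 UMIs per gene (95.2), left out genes under 0.2 of their highest level (87.4) or defined classes by the WT library (96.1). It rests on few genes and on 216 WT cells, and thinning to 2787 UMIs per cell leaves 2588 KO and 64 WT cells.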

How the results depend on the processing

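Shares among cells other than neutrophils, list genes at 0.2 or more of their highest level, and lists without the interferon-led clusters were alternatives chosen after the data were seen. No paired analysis was possible because each group is 1 library, and for the same reason no replicate could be left out. Of the alternative values, 106 of 133 for shares in bone marrow, 87 of 108 for shares in tumor, 69 of 125 and 89 of 121 for S100a8 and S100a9, 251 of 318 and 258 of 297 for lists, 345 of 423 and 355 of 449 for genes named by the rule, and 112 of 126 and 200 of 264 for other genes named (bone marrow before tumor) stayed within the counting or random range of the reported value. Of the others, 6 shares, 1 S100a9 value and 7 list values in bone marrow and 4 list values in tumor took the other direction, and the rest kept theirs or belong to a reported value whose range spans no difference. Low depth limits the tumor neutrophil-like class, which has 216 WT cells. The cause of each shift below was not tested.

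Ratios of shares (KO over WT) moved as follows. With at least 500 genes per cell they were 1.47 for bone marrow neutrophil-like, 1.87 for mature neutrophil-like and 0.222 for tumor conventional dendritic-like cells. With at most 5% mitochondrial UMIs the neutrophil-like ratios were 1.38, mature 1.48 and immature 0.937, the last in the other direction. At Leiden resolution 0.5 they were 1.62 for mature and 1.03 for immature neutrophil-like, 0.217 for conventional dendritic-like and 0.609 for CD8 T-like cells, and at resolution 2 it was 2.48 for tumor monocyte-like or macrophage-like cells. With S100a8 and S100a9 among the variable genes, mature neutrophil-like cells stood at 1.39 and immature ones at 0.904, in the other direction. With doublets kept, immature neutrophil-like cells stood at 0.981, in the other direction, monocyte-like or macrophage-like at 2.26, conventional dendritic-like at 0.289 and NK-like cells at 0.165. With the KO library clustered alone, immature neutrophil-like cells stood at 0.992, in the other direction, conventional dendritic-like at 0.230 and CD8 T-like cells at 0.475, and with the WT library alone monocyte-like or macrophage-like cells stood at 1.93. Among cells other than neutrophils, bone marrow B-lineage-like cells stood at 0.525, T-like or NK-like at 1.39 (0.873 as reported, with an interval of 0.754 to 1.01), and monocyte-like (1.36) and plasmacytoid dendritic-like cells (1.25) in the other direction. In tumor, monocyte-like or macrophage-like cells then stood at 2.97, conventional dendritic-like at 0.264, T-like at 0.531, CD8 T-like at 0.956, regulatory T-like at 0.36 and NK-like at 0.202.

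S100a9 ratios (KO over WT) are given for the whole bone marrow library, its immature and its mature neutrophil-like cells, the whole tumor library and tumor neutrophil-like cells, in that order. With S100a8, S100a9 and the mitochondrial, ribosomal and hemoglobin genes left out of the total they were 1.52, 1.08, 1.01, 23.7 and 1.18. With median-of-ratios scaling they were 1.70, 1.12, 0.999 (the other direction), 30.8 and 1.49. With thinned cells they were 1.63, 1.29, 1.09, 185 and 1.04, and as a mean over cells the values for the 4 groups up to the whole tumor library were 1.67, 1.26, 1.15 and 17.2. With doublets kept they were 1.60, 1.34, 1.19, 23.7 and 1.16. With the WT library alone defining the classes, immature cells stood at 1.31 and tumor neutrophil-like cells at 1.26. S100a8 in the whole tumor library (WT over KO) stood at 19.0 with thinned cells and 343 as a mean over cells. Thinning of the whole tumor libraries was to 3806 UMIs, which leaves out 2069 KO and 2108 WT cells.

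List medians relative to matched lists moved as follows. In immature neutrophil-like cells the type I interferon list stood at −0.44 with at least 200 UMIs per gene, −0.31 with genes at 0.2 or more of their highest level and −0.66 with doublets kept. In the other direction stood myeloid transcription factors of immature cells (0.017), G2 and M phase of mature neutrophil-like cells (0.14) the cytotoxic list of tumor monocyte-like or macrophage-like cells (0.59), secondary and tertiary granule of conventional dendritic-like cells (−0.013) and maturation and egress of plasmacytoid dendritic-like cells of bone marrow (−0.045) with genes at 0.2 or more of their highest level, and the last also with at least 200 UMIs per gene (−0.014). The same held with doublets kept for G2 and M phase of immature cells (0.041), secondary and tertiary granule of mature (0.066) and plasmacytoid dendritic-like cells (−0.21) and G2 and M phase of conventional dendritic-like cells (0.095), and with the WT library alone for the cytotoxic list of CD4 T-like cells (0.094). The inflammatory list of monocyte-like or macrophage-like cells stood at 0.63 with genes at 0.2 or more of their highest level. With doublets kept, the type I interferon list stood at −0.50 in mature neutrophil-like and −0.024 in NK-like cells, and G2 and M phase in plasmacytoid dendritic-like cells at 0.48. With the WT library alone the interferon list of plasmacytoid dendritic-like cells stood at −0.37. Without the interferon-led cluster, tumor monocyte-like or macrophage-like cells stood at −0.50 for the type I interferon and −0.52 for the interferon gamma list.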

Other observations

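The tests were chosen after the results were seen, apart from the comparison of S100a9 with 26 other neutrophil genes in tumor T-like cells and the share of S100a9 UMIs in the highest T-like cells, and the rule for genes shared by both tissues was also chosen afterwards. A few genes differed in the same direction in all compared classes of both tissues where they reached 0.2 of their highest level. Commd10, which encodes a protein of the COMMD family, was higher in KO in 7 classes of bone marrow (median log2 ratio 2.31, 1.40 to 5.12) and 7 of tumor (1.11, 0.32 to 2.24). Per the labels only KO mice carry Vav-Cre, so presence of Cre and loss of S100a8 cannot be told apart for this or any other gene. Cdk5rap1 was higher in 4 and 7 classes (medians 1.26 and 0.77), and Spp1, the osteopontin gene, in 3 and 3 (0.65 and 1.87). The interferon-inducible Xaf1 was lower in KO in 10 and 7 classes (medians −0.63 and −0.85), Ifi213 in 4 and 7 (−0.72 and −1.17), Ifi206 in 4 and 7 (−0.59 and −1.36), Ifi214 in 3 and 4 (−1.25 and −0.85) and Oas1g in 3 and 3 (−0.63 and −1.59).

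Sex-linked genes had low Xist in the 4 libraries, with 4 UMIs in KO and 2 in WT bone marrow and 4 in KO and 41 in WT tumor. The Y-linked Ddx3y stood at 69.8 and 50.6 CPM in bone marrow and 90.0 and 70.0 in tumor, KO before WT. Of the 85 S100a8 UMIs over all KO tumor barcodes, 69 lay in 1 mature neutrophil-like barcode of 6885 UMIs, which also held 173 S100a9 UMIs. Its S100a8 level of 10022 CPM lies near the median of WT tumor mature neutrophil-like cells (12459), and its barcode does not occur in the WT tumor library.

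Type I interferon genes were lower in the KO library in both tissues, with the list below the 2.5th percentile of random lists in 17 of 18 classes. With each cell thinned to the same number of UMIs this held in 13 of 18 classes, which argues against depth per cell as the whole cause, with B-like (percentile 2.64), T-like or NK-like (37.4), erythroid-like (13.1) and stem and progenitor-like cells (61.8) of bone marrow and regulatory T-like cells of tumor (38.2) as the exceptions. Without the interferon-led cluster, the list in tumor monocyte-like or macrophage-like cells stayed at a median log2 ratio of −0.65 (random lists −0.25 to −0.03, 52 genes), which argues against that cluster alone in this class. Bone marrow mature neutrophil-like cells also hold an interferon-led cluster, cluster 10, with 315 KO and 241 WT cells. Most of the Ifit3 difference there went away without it, as given above, and the list without it is not given here. With genes under 0.2 of their highest level left out, 17 of 18 classes again lay below the 2.5th percentile (stem and progenitor-like cells at 29.8), which argues against free RNA of interferon-high cells as the whole cause. An effect of the genotype and a difference between the pools of mice, such as exposure or handling, stay open, because each genotype is 1 pool per tissue.

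Neutrophil and myeloid suppressor genes were higher in T-like cells of the KO tumor, where 41.1% of cells had an S100a9 UMI, although the suppressor list lay inside the random range (0.063, percentile 73.1) with genes under 0.2 of their highest level left out. If free neutrophil RNA with the make-up of the captured neutrophil-like cells were the source, S100a9 would imply the same share of it as other neutrophil genes absent from WT T-like cells, and over the 7 genes with at most 3 UMIs there the ratio of these shares was 0.445 (Poisson range 0.367 to 0.828), which spans the 2-fold bound and decides nothing. Over a wider set of 26 genes the ratio was 0.370 (0.290 to 0.393), but some of these are made by WT T-like cells (Ccrl2 at 50.3 and Ccl3 at 33.7 CPM), which raises their implied shares, so this value excludes nothing either. S100a9 stood at 80.3 to 115 CPM in T-like (95.5), gamma-delta T-like or type 2 innate lymphoid-like (93.3), NK-like and fibroblast-like cells of the KO tumor. It stood at 164 in the mixed T and NK clusters, 241 in monocyte-like and macrophage-like cells together and 256 in conventional dendritic-like cells. In plasmacytoid dendritic-like cells it stood at 702, over 26 KO cells only. The levels in CPM thus differ between classes, whose KO median depths ran from 5144 to 51730 UMIs, and free RNA stays open as a source in part. The 59 T-like cells with the most S100a9 held 26.2% of its 722 UMIs, against 23.7% if UMIs fell at random, which argues against doublets with neutrophils.

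S100a9 and S100a6 were higher in CPM in KO immature neutrophil-like cells of bone marrow. With S100a8 alone left out of the total, the log2 ratio of S100a9 went from 0.38 to 0.093 (0.090 to 0.096), an interval above 0. It spans the bound of 0.095, a set part of the first value chosen after the result, so that bound decides nothing. Most of the S100a9 difference in CPM thus went with the loss of S100a8 from the total, while the cause of the rest stays open. This rescaling shifts the log2 ratios of all genes by the same amount, so for S100a6 it is a calculation and not a test. The log2 ratio of S100a6 went from 2.44 to 2.16 (2.14 to 2.18), so the scaling accounts for only a part of its difference. The median of 17 measured genes within 500 kb of S100a8 lay at percentile 77 of random lists, which decides nothing about an effect over the window. In immature cells 10 of these lay above and 7 below the class median. S100a7a was 19.6-fold higher there (6.52 to 96.4, 3 UMIs in WT), S100a1 2.16-fold and S100a13 1.94-fold higher. In mature cells the median lay above the random range, at percentile 99.2 over 15 genes, 9 above and 6 below the class median. S100a7a was 16.9-fold higher there (3 UMIs in WT), S100a1 6.27-fold (5 UMIs in WT) and S100a13 2.17-fold higher. S100a4, at 62.9 kb nearer to S100a8 than S100a1 and S100a13, stood at ratios of 1.04 (0.638 to 1.72) in immature and 0.734 (0.460 to 1.20) in mature cells. An effect of the deleted allele on neighboring genes may remain, as may a difference between the pools of mice.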
